A study of Homo sapiens with 23 samples.

How the data were processed

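Chromatin was prepared from SH-SY5Y cells. The labels' protocols describe 10 µM retinoic acid for 4 days and then 50 ng/mL BDNF in medium without serum for 3 days. Day 0 and day 3 are counted from the start of BDNF, so cells of day 0 had not had the 3 days of BDNF. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 minutes, chromatin was sonicated to fragments of 300 to 800 bp, fragments of 300 to 600 bp were selected on a gel after amplification, and single-end reads of 50 bp were sequenced. Fragments of this size limit how finely a binding position can be placed. PCR copies are not independent molecules, and whether copies were removed is not given in the sources used here.

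The files used are 5 peak lists, 1 per library, so the authors called peaks per sample and not on pooled samples. Per the submitters' processing notes, CASAVA and Bowtie 1.0.0 were used and the builds hg19 and mm9 were named. The lists hold chromosomes 20, 21 and 22, which the mouse genome lacks, and were therefore read as hg19. The peak caller, its threshold, the input library behind each list, and the number of reads per library are not given in the sources used here. Each row of the deposited lists gives a start, an end, a length that equals end minus start plus 1, and a summit offset. The deposited number of tags per peak is a whole-number count that was not normalized. The deposited fold enrichment is a ratio made by the authors' caller, and what it is relative to is not stated in the file headers. The deposited score column lost its name in the file header and is treated as a score without a unit. It was used to rank peaks within a list, and the lowest scores of the lists were also compared and used as a cut across lists, which takes the score to mean the same in each list and was not tested. Scores and folds are the authors' values and were not compared between libraries as measures of binding. A pair of lists called against the same input may share peaks that come from it, which could raise an overlap above chance, and this was not tested.

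Groups were taken from the sample titles and labels, with 1 sample per group. The designs, the pairs of lists, the rule for named regions and the alternatives were fixed before the data were examined, except where the text says otherwise. The deciles, 1 Mb windows, clusters, shares per chromosome and the relations between more than 2 lists were chosen after. For each pair, a peak of 1 list was counted as shared when a peak of the other overlapped it by at least 1 bp. Its share is given with an exact (Clopper-Pearson) 95% binomial interval, and counts per window with an exact Poisson interval. Peaks are not fully independent, so both cover counting error only. Chance was measured by moving all peaks of a chromosome by the same random offset, wrapping at the last peak end over all lists, 1000 times with a fixed seed. These shifts keep the spacing of peaks but can place them in stretches that reads cannot be aligned to or that are never open, so true chance may lie higher. Score deciles were formed within each list. A comparison at the same score deciles weights the share among the other peaks by the deciles of the peaks in question. It matches neither the score within a decile nor the peak length, so differences in these may remain. Chromosomes were split into a proximal part, with the lower coordinates, and a distal part at the widest gap between peaks of all lists. Only parts with at least 100 LSD1 peaks of control cells at day 3 were kept for ranking, which left 40. A quotient of ratios between parts has a 95% interval on the log scale from the 4 peak counts. Clusters are runs of at least 10 peaks of a list with gaps of at most 25 kb. The overlap and shift functions were run on simulated data, with the largest difference from the planted or expected share at 0.0116 points for LSD1 by day and 0.140 points for SVIL against LSD1. Planted peaks were sorted with the same overlap function, and the simulated peaks were placed uniformly. This checks the code only and not how the shifts act on peaks spaced as in the real lists.

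Named regions are, for each pair, the 10 overlapping regions with the best worse rank of the 2 lists and the 10 highest scoring peaks found in 1 list only, of which the text gives those at the top. Regions in all 5 lists, windows and clusters were named after their values were seen. Alternatives were a reciprocal overlap of 50%, edges at most 1 kb apart, the upper 50% of each list by score, the same number of top-scoring peaks, autosomes and X only, uniform random placement, a fold of at least 1.5 times the lowest and merging within 1 kb. Added after the data were seen were the lowest SVIL score applied to both lists and leaving out clustered regions. Planned shares at promoters, genes near peaks by gene list and motif contents were not run, because no genome or annotation of hg19 was used here and the gene table at hand is on another assembly. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.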

Results

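The series profiled chromatin binding by ChIP-seq in SH-SY5Y cells, a human neuroblastoma line that takes on neuronal features when it is treated with retinoic acid and then with brain-derived neurotrophic factor (BDNF). Antibodies were directed at LSD1 (KDM1A), a lysine demethylase, at its neuronal splice isoform LSD1+8a, at supervillin (SVIL), an actin-binding protein that the series design names as a cofactor of LSD1+8a, and at histone H3 dimethylated at lysine 9. Cells carried a control shRNA or an shRNA against a target, and most samples were taken at day 0 or day 3 of BDNF treatment, with some of the samples for dimethylated lysine 9 at a further stage that the labels call D0. The series has 23 samples, of which 14 are ChIP and 9 are input samples. Peak lists of 5 ChIP samples were analysed here. They are LSD1 in control cells at day 0, LSD1 in control cells at day 3, LSD1 in LSD1+8a knockdown cells at day 0, LSD1+8a in control cells at day 3 and SVIL in control cells at day 3. The other 9 ChIP samples, including all 5 for dimethylated lysine 9, were not analysed here. Among them are LSD1+8a samples from LSD1+8a knockdown cells and a SVIL sample from SVIL knockdown cells. The specificity of these antibodies was therefore not checked. Each group is 1 library, so no difference below has a replicate check and no test between conditions was possible. Intervals in parentheses are exact 95% binomial intervals on the number of peaks and cover counting error only. Positions are in the hg19 build and carry no gene names, because no annotation of that build was used here.

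The lists differed widely in length. LSD1 in control cells had 16882 peaks at day 0, covering 15.2 Mb, and 20748 peaks at day 3, covering 24.1 Mb. LSD1 in knockdown cells at day 0 had 10248 peaks over 8.32 Mb. LSD1+8a at day 3 had 3378 peaks over 3.01 Mb and SVIL had 1452 peaks over 0.488 Mb. SVIL peaks were the narrowest, with a median length of 314 bp, against 831 bp for LSD1+8a and 1044 bp for LSD1 on the same day. The median number of tags per peak was 26 and 50 for LSD1 in control cells at day 0 and day 3, 28 for LSD1 in knockdown cells, 38 for LSD1+8a and 20 for SVIL. The total number of reads per library is not given in the sources used here, so a shorter list cannot be told from a shallower library. The SVIL list also began at a higher score, 71.7, than the other lists, whose lowest score was 50.0.

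Peaks of all lists merged into 32188 regions. Of these, 18547 (57.6%) lay in 1 list, 8578 in 2, 3793 in 3, 1131 in 4 and 139 in all 5. Regions listed for LSD1 in control cells at day 3 alone were the most frequent kind, with 10795. The regions in all 5 lists with the best ranks were on chromosome 21 (9825316 to 9827962), chromosome 1 (156185832 to 156186811) and chromosome 17 (76249931 to 76250963). The chromosome 21 region had very many tags, 3197 for LSD1 at day 3 and 1093 for SVIL, but a fold enrichment of only 11.8 and 6.75. The chromosome 1 region had 172 tags at a fold of 5.82 for SVIL and 297 at 11.7 for LSD1+8a. Both folds lay below the list medians of 18.2 and 15.2. For LSD1 its folds were 24.0 at day 3, and 16.6 in control and 16.2 in knockdown cells at day 0. These lay above the list medians of 17.05, 9.3 and 9.13. No regions of high signal were left out here, and the inputs were not examined at these regions. Binding there was therefore not told apart from signal that arises whatever the antibody. The same holds for the shared regions named below.

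**Figure D1:**
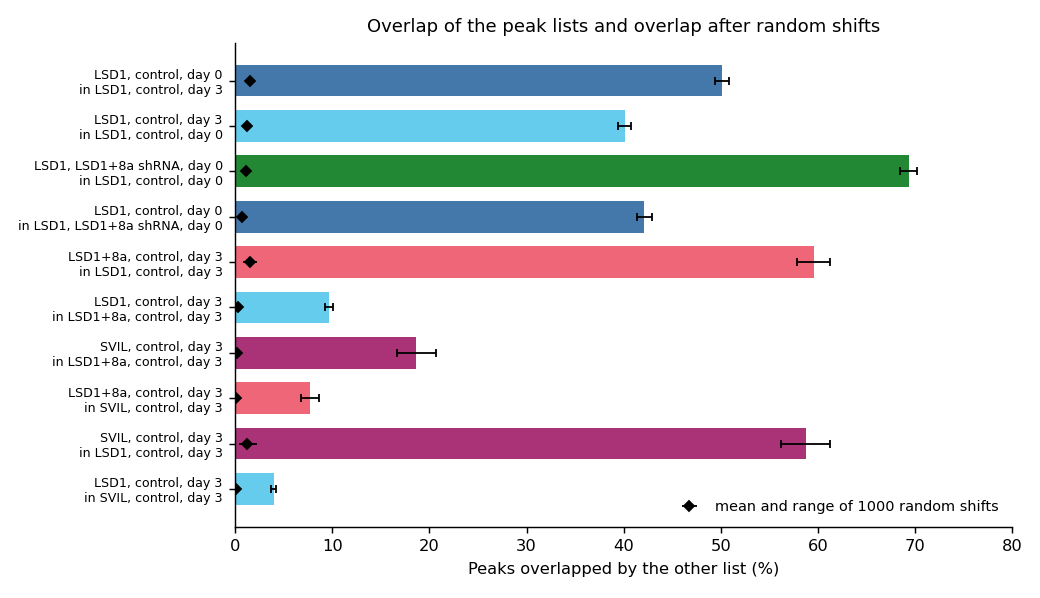
Share of the peaks of each list (vertical axis, first line of each label) that were overlapped by at least 1 bp by a peak of another list (second line), in percent (horizontal axis), for the 5 pairs of lists in both directions. Bars are 1 library each with exact 95% binomial intervals, and diamonds with lines are the mean and range of 1000 random shifts; every bar lies above the range of its shifts, from 3.97% for LSD1 at day 3 in SVIL to 69.4% for LSD1 in knockdown cells in LSD1 of control cells.

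The first comparison asked how LSD1 binding in control cells differed between day 0 and day 3 of BDNF. Of the 16882 day 0 peaks, 8461 (50.1%, 49.4 to 50.9) overlapped a day 3 peak, and 8320 of the 20748 day 3 peaks (40.1%, 39.4 to 40.8) overlapped a day 0 peak. Random shifts of the day 0 peaks gave 1.498% on average and at most 1.81%. LSD1 peaks on chromosome 19, the most gene-dense human chromosome, were fewer on day 3, with 484 of all peaks (2.33%, 2.13 to 2.55) against 877 (5.19%, 4.86 to 5.54) on day 0. Among the 1452 highest scoring peaks of each list, the chromosome 19 share was 2.07% (1.398 to 2.94) on day 3 and 12.5% (10.8 to 14.3) on day 0. Of the day 0 peaks on chromosome X, 31.3% (25.6 to 37.5) overlapped a day 3 peak, as did 35.6% (32.4 to 38.8) on chromosome 19, 41.5% (35.3 to 47.9) on chromosome 22, 42.3% (38.2 to 46.4) on chromosome 16, 42.5% (37.7 to 47.5) on chromosome 20 and 56.9% (53.3 to 60.4) on chromosome 8, the highest share but for the 2 peaks on chromosome Y.

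Among 1 Mb windows, chosen after the data were seen, the window from 10 to 11 Mb of chromosome 19 had 29 LSD1 peaks on day 0 (exact Poisson interval 19.4 to 41.6) and 9 (4.12 to 17.1) on day 3. The window from 30 to 31 Mb of chromosome 16 had 31 (21.1 to 44.0) and 14 (7.65 to 23.5). In the other direction, the window from 40 to 41 Mb of chromosome 6 had 3 peaks (0.619 to 8.77) on day 0 and 22 (13.8 to 33.3) on day 3. The windows from 125 to 126 Mb of chromosome 10 and from 127 to 128 Mb of chromosome 11 held no day 0 peak and 17 and 14 day 3 peaks. The best ranked regions present on both days, after the chromosome 21 region, were on chromosome 1 (156185832 to 156186785 on day 0), chromosome 16 (30932873 to 30935123), chromosome 17 (31149294 to 31150230) and chromosome 19 (42746644 to 42747791). The highest scoring peak of day 0 without a day 3 overlap was on chromosome 11 (94179981 to 94180747), with 156 tags and a fold enrichment of 193, and had no overlap in any other list. Another, on chromosome 18 (47813795 to 47814800, 217 tags), had overlaps in 2 other lists. The highest scoring peaks of day 3 without a day 0 overlap were on chromosome 15 (40615305 to 40616149, 196 tags), chromosome 17 (32303479 to 32304642, 166 tags) and chromosome 13 (99735908 to 99737472, 188 tags).

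Peaks with higher scores were shared more often. The share of day 0 peaks overlapped on day 3 rose from 35.3% (33.03 to 37.6) in the lowest score decile to 64.2% (61.9 to 66.5) in the highest, and the share of day 3 peaks overlapped on day 0 from 25.5% (23.6 to 27.4) to 74.0% (72.03 to 75.9). Where day 0 and day 3 peaks overlapped, their summits lay a median of 69 bp apart. The titles of the 3 day 3 libraries used here carry no library number, unlike those of the day 0 libraries and of other day 3 libraries in the series, so a difference of library batch cannot be told apart from the day in this pair. A difference of input cannot be told apart from the day either, since the input behind each list is unknown. Control cells at day 3 have an input in the series only among those labelled for the dimethylated histone. Outside that set, control cells have an input at day 0 and none at day 3. The 3 day 3 lists used here therefore lack an input of the same cells and day outside that set, unlike the day 0 lists. The comparison holds 1 library on each side, and no value within a batch can be had.

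**Figure D2:**
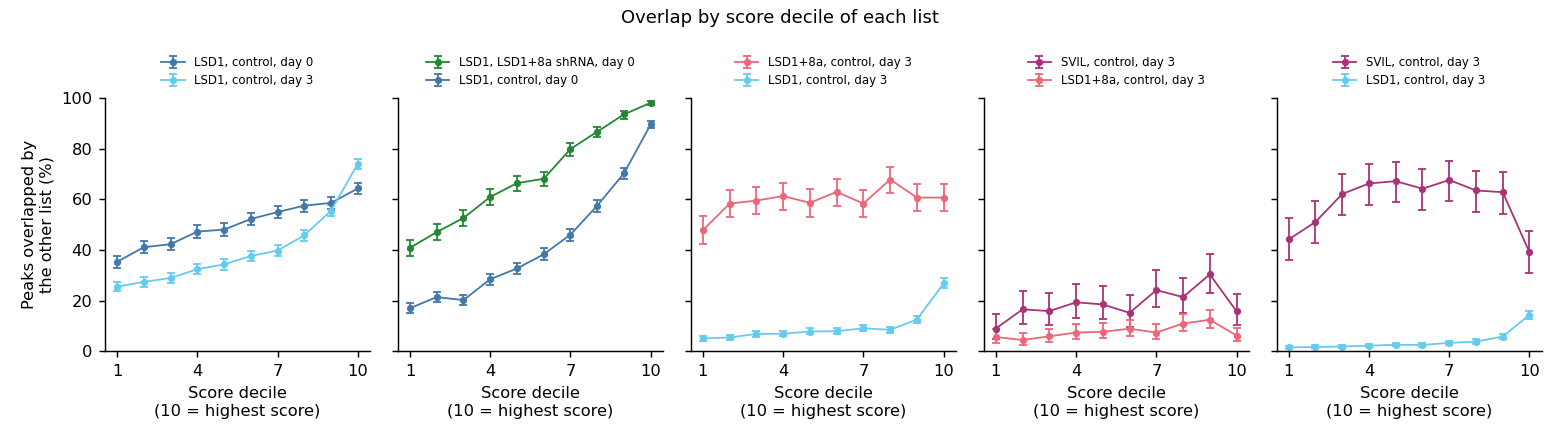
Share of peaks overlapped by the other list of the pair (vertical axis, percent) by score decile within each list (horizontal axis, 10 is the highest), in 1 panel per pair, with exact 95% binomial intervals. From the lowest to the highest decile, sharing rose in both LSD1 pairs, up to 98.0% for the knockdown list. SVIL set against LSD1 stood at 44.1% in the lowest decile, 67.6% in decile 7 and 39.0% in the highest.

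The second comparison asked how LSD1 binding at day 0 differed between LSD1+8a knockdown and control cells. Nearly all strong LSD1 peaks of knockdown cells were also listed in control cells, and the control list was longer. Of the 10248 knockdown peaks, 7109 (69.4%, 68.5 to 70.3) overlapped a control peak, against 1.12% after random shifts. Of the 16882 control peaks, 7111 (42.1%, 41.4 to 42.9) overlapped a knockdown peak. In the highest score decile these shares were 98.0% (97.0 to 98.8) and 89.5% (88.0 to 90.9), and in the lowest 40.8% (37.8 to 43.9) and 17.002% (15.2 to 18.9). Summits of overlapping peaks lay a median of 49 bp apart, the smallest distance of the 5 pairs.

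Control peaks missing from the knockdown list included the 2 highest scoring peaks of the control list, on chromosome 8 (23004357 to 23007916, 1802 tags, fold enrichment 218, and 23011175 to 23012869, 692 tags, fold enrichment 137). Each had overlaps in the 3 other lists. Next came the chromosome 11 peak named above and a peak on chromosome 3 (17443239 to 17444110, 147 tags), neither with an overlap in any other list. Of the 10 highest scoring control peaks without a knockdown overlap, the remaining ones were a second chromosome 11 peak (94178863 to 94179242) and 5 peaks on chromosome 10 between 29759094 and 29840597. These 5 belong to a cluster of 19 control peaks on chromosome 10 (29751111 to 29843994), of which none was found in the knockdown list (0 to 17.6%). The whole window from 29 to 30 Mb of chromosome 10 had 28 control peaks (18.6 to 40.5) and 3 knockdown peaks (0.619 to 8.77). The window from 30 to 31 Mb of chromosome 16 had 31 peaks in each list. The highest scoring knockdown peak without a control overlap, on chromosome X (77358961 to 77360159, 87 tags), ranked only 310 in its list, and the next, on chromosome 17 (4869869 to 4871920, 88 tags), ranked 316.

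**Figure D3:**
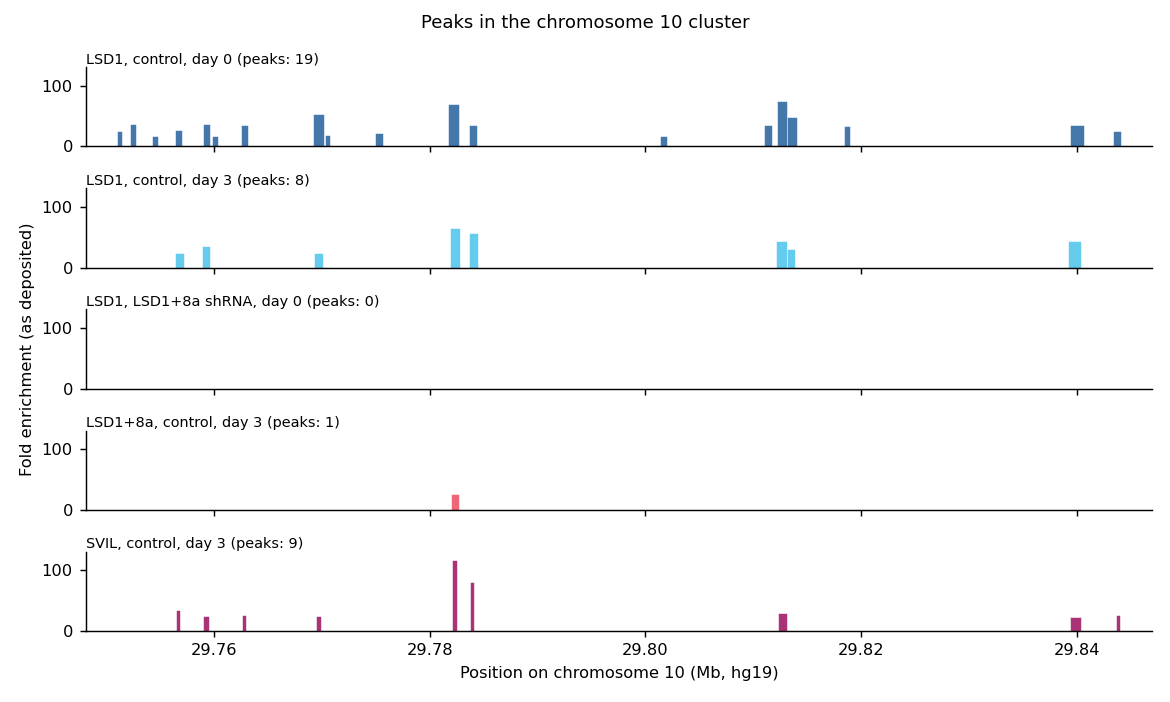
Peaks of the 5 lists in the cluster on chromosome 10, by position (horizontal axis, Mb, hg19) and deposited fold enrichment (vertical axis), with bar widths equal to peak lengths. LSD1 in control cells had 19 peaks at day 0 and 8 at day 3, LSD1 in knockdown cells 0, LSD1+8a 1 and SVIL 9.

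Control peaks that lay at a day 3 LSD1+8a peak were found in the knockdown list more often than others. The share was 73.3% (71.4 to 75.2) of 2074 such peaks, against 37.7% (37.0 to 38.5) of the 14808 others and 52.3% of others at the same score deciles, and it was higher in 10 of 10 deciles. For the 715 control peaks at a SVIL peak it was 60.4% (56.7 to 64.0), against 41.3% (40.6 to 42.1) of the others and 55.0% at the same deciles, and higher in 8 of 10. For the 8461 control peaks at a day 3 LSD1 peak it was 43.7% (42.7 to 44.8), above the 40.5% (39.5 to 41.6) of the 8421 others but below the 48.7% of others at the same deciles, and higher in 2 of 10 deciles. These are 3 of 8 such relations, all chosen after the data were seen. Score within a decile and peak length were not matched in them. The LSD1+8a list comes from day 3 and the knockdown from day 0, and the extent of the knockdown was not measured in the lists used here. With unknown depth, the loss of weaker control peaks cannot be told apart from a shallower library.

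The third comparison set LSD1+8a against LSD1 in control cells at day 3. Of the 3378 LSD1+8a peaks, 2012 (59.6%, 57.9 to 61.2) overlapped an LSD1 peak, against 1.52% after random shifts, and 2011 of the 20748 LSD1 peaks (9.69%, 9.29 to 10.1) overlapped an LSD1+8a peak. The strongest LSD1+8a peaks were shared about as often as those of middle score. The share was 60.7% (55.2 to 65.9) in the highest score decile and 58.6% (53.1 to 63.9) in the fifth, with 47.8% (42.3 to 53.3) in the lowest. Among LSD1 peaks, the share rose from 5.06% (4.16 to 6.10) to 26.8% (24.9 to 28.8). When the same number of top-scoring peaks was taken from both lists, 22.1% of the LSD1+8a peaks were shared.

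The best ranked shared regions were on chromosome 19 (42746488 to 42747723 for LSD1+8a, 122 tags), chromosome 1 (156186140 to 156186756, 297 tags), chromosome 18 (77438962 to 77440147, 138 tags) and chromosome 6 (26122946 to 26123697, 72 tags). LSD1+8a peaks without an LSD1 overlap included those ranked 2, 4 and 5 in the LSD1+8a list, on chromosome 18 (77748080 to 77749087, fold enrichment 157), chromosome X (149106330 to 149107072, fold enrichment 142) and chromosome 7 (50517729 to 50518616, fold enrichment 66.3). The chromosome X peak had no overlap in any list. LSD1 peaks without an LSD1+8a overlap included those on chromosome 1 (49119822 to 49121196, 334 tags), chromosome 15 (40615305 to 40616149) and chromosome 9 (16266512 to 16269406, 281 tags). In the window from 124 to 125 Mb of chromosome 5, LSD1 had 38 peaks (26.9 to 52.2) and LSD1+8a had none, and from 208 to 209 Mb of chromosome 1 LSD1 had 32 (21.9 to 45.2) and LSD1+8a none. From 30 to 31 Mb of chromosome 16, both had 14 peaks, which was 4.14 per 1000 LSD1+8a peaks and 0.675 per 1000 LSD1 peaks. Of the 1366 LSD1+8a peaks without a day 3 LSD1 overlap, 841 (61.6%, 58.9 to 64.2) overlapped a day 0 LSD1 peak of control or knockdown cells. Only 525 LSD1+8a peaks (15.5%, 14.3 to 16.8) lay outside all 3 LSD1 lists.

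The fourth comparison set SVIL against LSD1+8a in control cells at day 3. Of the 1452 SVIL peaks, 270 (18.6%, 16.6 to 20.7) overlapped an LSD1+8a peak, and 260 of the 3378 LSD1+8a peaks (7.70%, 6.82 to 8.65) overlapped a SVIL peak. Random shifts of the SVIL peaks gave 0.171% on average and at most 0.689%. The observed share was 109 times the chance share. For SVIL against LSD1 it was 49.7 times the chance share, and for the other pairs 33.5 to 62.1 times, each for the shorter list. A lower chance share allows a larger ratio, and this pair had the lowest, so these ratios do not rank the pairs. With the same number of top-scoring peaks, 17.2% of SVIL peaks lay at LSD1 peaks (chance share 0.118%). For LSD1+8a that share was 9.30% (chance share 0.0768%). The strongest SVIL peak, on chromosome 17 (76249964 to 76250726, 214 tags, fold enrichment 94.4), and the second, on chromosome 11 (62608795 to 62609414, 124 tags), lay at LSD1+8a peaks. Other well ranked shared regions were on chromosome 6 (26189127 to 26189476 for SVIL), chromosome 3 (156877889 to 156878304) and chromosome 17 (61509257 to 61509780).

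SVIL peaks without an LSD1+8a overlap were led by peaks on chromosome 6 (10778519 to 10778930, 76 tags, fold enrichment 72.6), chromosome 17 (75678000 to 75678617, 87 tags) and chromosome 17 (80908574 to 80909276, 98 tags). The strongest LSD1+8a peak, on chromosome 17 (80605824 to 80606757, 214 tags, fold enrichment 189), had overlaps in the 3 LSD1 lists and none in the SVIL list. The window from 30 to 31 Mb of chromosome 16 had 14 LSD1+8a peaks (7.65 to 23.5) and no SVIL peak, and that from 29 to 30 Mb of chromosome 2 had 11 SVIL peaks (5.49 to 19.7) and 5 LSD1+8a peaks (1.62 to 11.7). SVIL peaks in the ninth score decile overlapped LSD1+8a most often, in 30.3% (22.99 to 38.5), and those in the highest in 15.8% (10.3 to 22.7). With the same number of top-scoring peaks from both lists the share was 9.30%, with the lowest SVIL score applied to both 9.71%, and with a reciprocal overlap of 50% of each peak 4.68%. The chance share was 0.0768% with the same number of top-scoring peaks, and was not computed for the other settings named here.

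The fifth comparison set SVIL against LSD1 in control cells at day 3. Of the 1452 SVIL peaks, 853 (58.7%, 56.2 to 61.3) overlapped an LSD1 peak, against 1.18% after random shifts and at most 2.27%, and 824 of the 20748 LSD1 peaks (3.97%, 3.71 to 4.25) overlapped a SVIL peak. The strongest SVIL peaks were shared less often, with 39.0% (31.1 to 47.5) in the highest score decile against 62.8% (54.3 to 70.6) in the ninth. Among LSD1 peaks the share rose from 1.54% (1.06 to 2.17) in the lowest decile to 14.4% (12.9 to 15.9) in the highest. Of the SVIL peaks, 234 (16.1%) overlapped both the LSD1 and the LSD1+8a list, 619 (42.6%) the LSD1 list alone, 36 (2.48%) the LSD1+8a list alone and 563 (38.8%) neither. Whether the LSD1 antibody also binds LSD1+8a, a form of the same protein, was not examined here. These classes therefore describe lists and not binding by 1 isoform. LSD1 peaks at an LSD1+8a peak were overlapped by SVIL in 228 of 2011 cases (11.3%, 9.98 to 12.8), against 3.18% (2.93 to 3.44) of the others and 5.13% of others at the same score deciles. The highest decile of LSD1 peaks held scores from 243 to 3100, and peak length was not matched. Stronger or longer peaks may therefore account for part of this difference, which was not tested.

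Shared regions with the best ranks included those on chromosome 11 (62608795 to 62609414 for SVIL), chromosome 3 (64598513 to 64598980), chromosome 7 (133433081 to 133434235), chromosome 8 (126346330 to 126346865), chromosome 2 (29873546 to 29874268) and chromosome 6 (26104095 to 26104555). SVIL peaks without an LSD1 overlap included those on chromosome 6 (10778519 to 10778930), chromosome 12 (27788359 to 27788852, 58 tags), chromosome 1 (212070796 to 212071279, 68 tags) and chromosome 20 (51054331 to 51054833, 57 tags), none of which had an overlap in any list. LSD1 peaks without a SVIL overlap included the second strongest of the LSD1 list, on chromosome 19 (42746396 to 42747899, 419 tags), and peaks on chromosome 16 (30932772 to 30934917, 407 tags) and chromosome 19 (47353742 to 47354780, 242 tags). SVIL peaks lay on chromosome 7 in 12.4% (10.7 to 14.2) of cases, against 6.47% (6.14 to 6.81) of LSD1 peaks, and on chromosome 1 in 15.1% (13.3 to 17.03) against 10.1% (9.74 to 10.6). For the 1452 highest scoring LSD1 peaks these shares were 7.78% (6.46 to 9.28) and 12.1% (10.5 to 13.9), so that the intervals overlapped for chromosome 1. The share of SVIL peaks on LSD1 peaks fell to 17.2% when the same number of top-scoring peaks was taken from both lists. The chance share was then 0.118%. The observed share fell to 1.72% for a reciprocal overlap of 50%. The difference in length between SVIL and LSD1 peaks, with medians of 324 and 1373 bp where they overlapped, leaves little room to meet that setting.

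**Figure D4:**
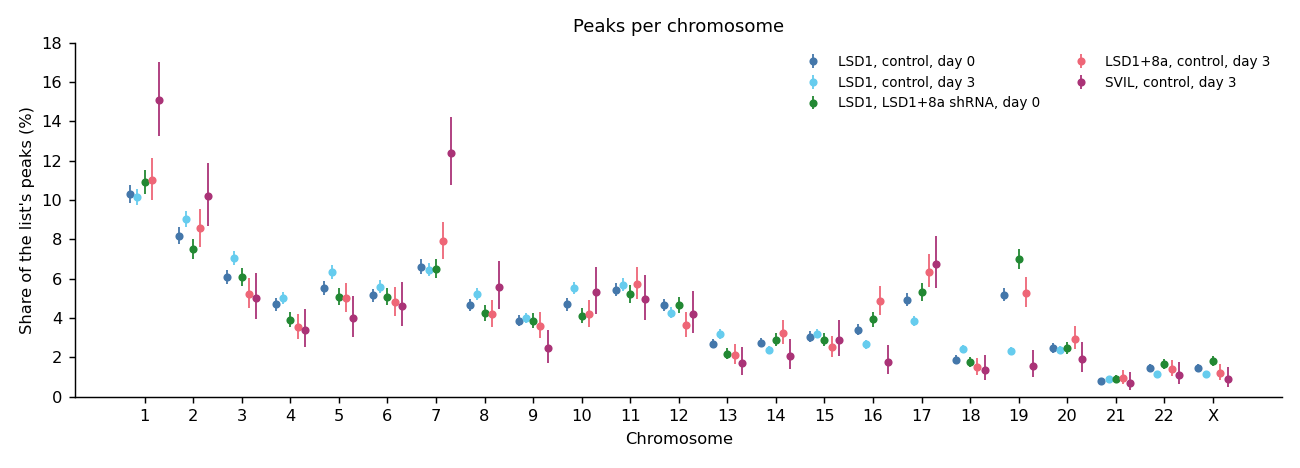
Share of each list's peaks on each chromosome (vertical axis, percent; horizontal axis, chromosome) with exact 95% binomial intervals; each point is 1 library. SVIL stands above the other lists on chromosome 7 at 12.4%, and LSD1 at day 3 and SVIL lie below the others on chromosome 19 at 2.33% and 1.58%.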

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

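Applying the lowest SVIL score to both lists and leaving out clustered regions were chosen after the data were seen. In the order LSD1 by day, LSD1 by knockdown, LSD1+8a against LSD1, SVIL against LSD1+8a and SVIL against LSD1, the shares were 50.1%, 69.4%, 59.6%, 18.6% and 58.7%. With a reciprocal overlap of 50% they became 41.4%, 64.5%, 48.5%, 4.68% and 1.72%. With the same number of top-scoring peaks they became 44.1%, 55.7%, 22.1%, 9.30% and 17.2%. The upper 50% of each list by score gave 38.6% for LSD1 by day, 40.6% for LSD1+8a against LSD1, 12.8% for SVIL against LSD1+8a and 47.0% for SVIL against LSD1, and the knockdown share moved by less than its interval. The lowest SVIL score moved the same 4 shares to 44.9%, 49.8%, 9.71% and 50.8%. For the upper 50% of each list the chance shares fell too, and by a larger proportion than the observed shares. In the order of pairs above, they fell from 1.498%, 1.12%, 1.52%, 0.171% and 1.18% to 0.866%, 0.708%, 0.844%, 0.0884% and 0.671%. Edges at most 1 kb apart gave 52.3% for LSD1 by day and 71.4% for the knockdown, with the other 3 inside their intervals. A reciprocal overlap asks more of each overlap, and the same number of top-scoring peaks shortens only the longer list, so these can only lower a share, and wider edges can only raise it. For the settings that trim both lists by score, the cause was not tested. Autosomes and X only, and leaving out clustered regions, moved none of the 5 shares by more than its interval, and uniform placement moved no chance share by more than 1 SD of the shifts. No list held more than 3 peaks on chromosome Y, so leaving these out could hardly move a share. The 5 numbers of peaks stayed within 1.5 times under a fold of at least 1.5 times the lowest and under merging within 1 kb. That fold cut left 16881 of 16882, 20532 of 20748, 9970 of 10248, 3313 of 3378 and 1436 of 1452 peaks. It removed so few that it says little about how the numbers depend on the fold. The alternatives for promoters, gene lists and motifs were not run. With 1 library per group and unknown depth, neither the differences in list length nor the absence of single peaks has an error between samples.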

Other observations

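The tests on chromosome 19, on extra copies at any score, on the length of the SVIL list, by window on the SVIL list and on the chromosome 10 cluster were chosen after their results were seen. The test by score on the SVIL list was chosen before.

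LSD1+8a peaks of day 3 were covered about as well by LSD1 peaks of day 0 as by those of day 3. Of the 3378 LSD1+8a peaks, 60.9% (59.2 to 62.5) overlapped an LSD1 peak of control cells at day 0 and 59.6% (57.9 to 61.2) at day 3. Cut to the 10248 highest scoring peaks, the length of the knockdown list, the LSD1 lists covered 48.0% (46.3 to 49.7) with control cells at day 0, 39.8% (38.1 to 41.5) with control cells at day 3 and 52.4% (50.7 to 54.1) with knockdown cells at day 0. SVIL peaks had another order at that length, with 41.1% (38.6 to 43.7), 44.2% (41.6 to 46.8) and 33.1% (30.7 to 35.6). LSD1 peaks of day 3 at an LSD1+8a peak were already listed at day 0 in 67.6% (65.5 to 69.7) of cases, against 46.7% of other peaks at the same score deciles, and those at a SVIL peak in 70.8% (67.5 to 73.8), against 51.4%. Score within a decile and peak length were not matched here either.

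There were 19 clusters in each LSD1 list of control cells, 2 in the knockdown list and none for LSD1+8a or SVIL. A longer list can more easily hold runs of at least 10 peaks, and clusters were not counted at equal list length. These counts therefore cannot tell a trait of a list from its length. A cluster on chromosome 6 (26156462 to 26286218) had 15 LSD1 peaks on each day in control cells, 9 in knockdown cells and 5 each for LSD1+8a and SVIL. One on chromosome 16 (30538058 to 30670709) had 10 LSD1 peaks in control cells at day 0 and 8 in knockdown cells, 1 LSD1 peak at day 3, 5 LSD1+8a peaks and no SVIL peak. One on chromosome 9 (134827058 to 134899442) had 10 LSD1 peaks at day 3, 3 at day 0 in control cells and none in the other lists.

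LSD1 peaks on chromosome 19 made up 5.19% of the list at day 0 and 2.33% at day 3. Chromosome 19 was not alone in this. The share also fell on chromosome 16, from 3.42% to 2.66%, and on chromosome 17, from 4.93% to 3.86%. It rose on chromosome 3, from 6.09% to 7.07%, and on chromosome 18, from 1.88% to 2.41%. Only chromosome 19 is followed below. A longer day 3 list that reaches lower scores is argued against, since the same number of top-scoring peaks gave 2.07% on day 3, below the lower bound of 10.8% for day 0. A library batch shared by the 3 day 3 libraries used here stays open, since their titles carry no library number while those of other day 3 libraries in the series do. If such a batch were the cause, all day 3 lists were predicted to lie at or below the LSD1 share of 2.33%. SVIL did, with 1.58% on chromosome 19, but LSD1+8a did not, with 5.27% (4.54 to 6.08). What LSD1+8a would have had without the batch is unknown. With 1 library per antibody these shares name no bound for LSD1, so the unmet prediction does not decide. The day of BDNF treatment, which goes with the titles in this pair, also stays open and was not tested. So does a different input behind each list. The batch, the input and the day cannot be told apart.

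SVIL peaks lay on chromosome 7, distal chromosome 1, proximal chromosome 2 and distal chromosome 17 in 34.8% (32.3 to 37.3) of cases, against 18.7% (18.2 to 19.2) of LSD1 peaks and 23.7% (22.3 to 25.2) of LSD1+8a peaks at day 3. As these chromosomes were picked for high SVIL shares, LSD1 peaks of day 3 were given their own 5 best of 40 parts: the shorter SVIL list is argued against, since the 1452 top-scoring LSD1 peaks exceeded the LSD1 share by 7.60 points there against 16.1 for SVIL, and so are a few dense windows, since counted once per 1 Mb window SVIL exceeded it by 10.2 points and 100 draws of LSD1 peaks by at most 4.69. SH-SY5Y is commonly described as carrying extra copies of these parts, which may raise the number of SVIL peaks called there, and this stays open: within a chromosome, the ratio of SVIL to LSD1 peaks on the part with extra copies was 1.82 times (1.36 to 2.44) that on the other part for chromosome 1 and 2.68 times (1.88 to 3.83) for chromosome 2, but 1.23 times (0.701 to 2.16) for chromosome 17, whose other part held 16 SVIL peaks. The 5 parts had the highest ratios of SVIL to LSD1 share of the 40 parts with at least 100 day 3 LSD1 peaks. Their ratios were 1.64 to 2.07, against at most 1.48 in the other parts kept, but given how they were picked this ranking is no test. Whether extra copies lift mainly weak peaks over the threshold stays open too, as the lower-scoring peaks of the SVIL list exceeded the upper by 2.07 points (-2.83 to 6.96), and neither copy number was measured here nor any biological explanation tested.

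The cluster of 19 narrow LSD1 peaks on chromosome 10 had a median length of 484 bp and a median fold enrichment of 32.98, against 763 to 1387 bp and 5.94 to 16.3 in the other 18 clusters of the same list. General loss of weaker peaks from the shorter knockdown list is argued against, since 74.2% of these peaks would be found there at the rate of their score deciles and none was (0 to 17.6%), while the other clusters had from 30% to 80%. DNA of another source, such as a construct, in the libraries that show the cluster may be a candidate explanation, with 9 SVIL peaks inside it as well, but it cannot be told apart from binding lost in the knockdown without exon positions or reads. The SVIL gene is on chromosome 10, and whether the cluster lies in it was not tested. Loss of LSD1 from these positions through the knockdown also stays open and was not tested.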
